A study of Homo sapiens with 8 samples.

How the data were processed

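MRC5 cells, a normal human lung fibroblast line, were left untreated or exposed to 12 J/m2 of UV-C and collected after 30 min, 3 h or 24 h of recovery, with 2 biological replicates per condition and 8 libraries in all. Per the labels, total RNA was extracted with the RNeasy kit and libraries were made with the NEBNext Ultra RNA kit from 1 µg of RNA. Whether the libraries were poly(A)-selected or stranded is not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5 for alignment to hg38 and featureCounts 1.5.0-p3 for counting. The deposited table holds raw counts per gene for each library, and the values were whole numbers. The same deposited table holds FPKM values, which divide the counts by gene length and by a scaled library total. In every library 1 total gave all FPKM values from the counts to a relative deviation below 1e-06, and this total was 0.8598 to 1.107 times the count total. The table holds 58735 genes, whose identifiers and coordinates all matched GENCODE release 29 (GRCh38), and 58708 names matched as well.

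Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of the 29753 genes with a count in any library, 15113 passed filterByExpr by group, of which 12545 were protein-coding. Library totals were scaled with trimmed mean of M-values (TMM) factors. One quasi-likelihood model (glmQLFit and glmQLFTest) with group as the only term was fitted to all 8 libraries, with 4 residual degrees of freedom, a common dispersion of 0.0148 and a median prior of 6.12 degrees of freedom. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The comparisons were each time after UV-C against Control, 3 h against 30 min, and 24 h against 3 h. Fold changes are log2 values with their standard error (SE), and levels are TMM-scaled CPM (counts per 1e6) as mean ± SD of 2 libraries. Total counts were 17552411 to 18426371 per library, so that 3 counts, the upper limit that a count of 0 allows, were 0.154 to 0.199 TMM-scaled CPM, with 0.199 and 0.180 at 3 h. This limit covers counting error only.

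The main tests, the 22 gene lists and the rule for named genes were set before the data were examined. The lists were p53 targets, nucleotide excision repair, DNA damage signalling and replication stress, immediate early genes, inflammatory and NF-kB genes, interferon-stimulated genes, G2/M cell cycle genes, DNA replication and G1/S genes, replication-dependent histones, extracellular matrix genes, matrix proteases and inhibitors, integrated and unfolded protein stress response, heat shock and chaperone genes, chromatin modifiers and remodellers, RNA polymerase II and elongation factors, ribosomal proteins, mitochondrially encoded mRNAs, cholesterol synthesis, smooth muscle and myofibroblast markers, epithelial markers, endothelial markers and leukocyte markers. A list was tested when at least 5 members passed the filter, which left out the leukocyte markers and gave 21 tested lists. Each list was compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, and p values were adjusted by Benjamini-Hochberg over the tested lists. The correlation estimated for each list was used as an alternative, as was the directional test fry, which asks whether the members move one way on balance. Calls per gene were also adjusted over the list alone. XPC and DDB2 stand in both the p53 and the repair list, BTG2 in both the p53 and the immediate early list, and SESN2 in both the p53 and the stress response list. PCNA, LIG1, RFC2, RFC3 and RFC4 stand in both the repair and the replication list, and TCEA1 in both the repair and the RNA polymerase II list.

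Named genes were the 6 largest rises and the 6 largest falls against Control among called protein-coding genes with an average log2 CPM of at least 2 and both UV-C libraries beyond both Control libraries. They also included up to 4 members of each list with the lowest adjusted p. Between times, the 3 largest in each direction were named. For gene span, the median log2 fold change of protein-coding genes of at least 100 kb was compared with that of genes of at most 10 kb, and camera was run on the long genes.

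Alternatives were DESeq2 1.42.0 (its size factors in the edgeR model, and its Wald test), scaling by total counts only, no count filter, a replicate block, only the 2 groups compared, a fold change of at least 2, limma on log2 FPKM with a pseudocount of 1 or 0.1 for genes with a mean FPKM of at least 1, span limits of 50 kb and 20 kb, an average log2 CPM of at least 2 for the span comparison, and leaving out each library in turn. Leaving out both 3 h libraries and removing the GC trend of each library were added after the data were seen. Transcript GC content was that of the longest GENCODE transcript and was available for 15109 of the 15113 tested genes. Because the comparisons with Control share the same 2 Control libraries, 30 sets of unchanged groups sharing their controls were simulated. The test was checked on simulated data, in which it recovered 56.7% of 2-fold and 86.4% of 4-fold changes at the 30 min contrast and 71.6% and 87.9% at the 3 h contrast. Genes simulated without a change made up 6.78% and 11.3% of its calls, 8 and 17 genes, at a nominal 5%. Both contrasts were simulated from the Control means with the same dispersion for each gene. The gap between them therefore does not describe the 2 times, and the wider spread between the 3 h replicates was not reproduced. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.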

Results

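Gene expression was measured by RNA sequencing in MRC5 cells, a normal human lung fibroblast line, before and after UV-C, short-wavelength ultraviolet light that forms photoproducts in DNA. The series title names epigenetic signatures and nucleotide excision repair, the pathway that removes such photoproducts. There were 4 groups of 2 biological replicates: untreated cells (Control) and cells collected 30 min, 3 h and 24 h after 12 J/m2 of UV-C. Total counts were 18426371 and 17736780 in the Control libraries, 18091476 and 17552411 at 30 min, 17698953 and 18030837 at 3 h, and 17645729 and 17889753 at 24 h.

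The first principal component of log2 CPM held 45.9% of the variance and separated 3 h from 24 h, and the second held 29.8% and separated both times from Control and 30 min. Replicates differed by an SD of 0.15 log2 units in Control, 0.18 at 30 min and 0.16 at 24 h, but by 0.49 at 3 h. Between the 3 h replicates, 450 of 10349 protein-coding genes with an average log2 CPM of at least 2 differed more than 2-fold, against 6 or 7 in each of the other groups. The share of counts from mitochondrial ribosomal RNA was 0.0498% and 0.0562% in Control, 0.0766% and 0.0674% at 30 min, 0.220% and 0.358% at 3 h, and 1.00% and 0.881% at 24 h.

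**Figure D1:**
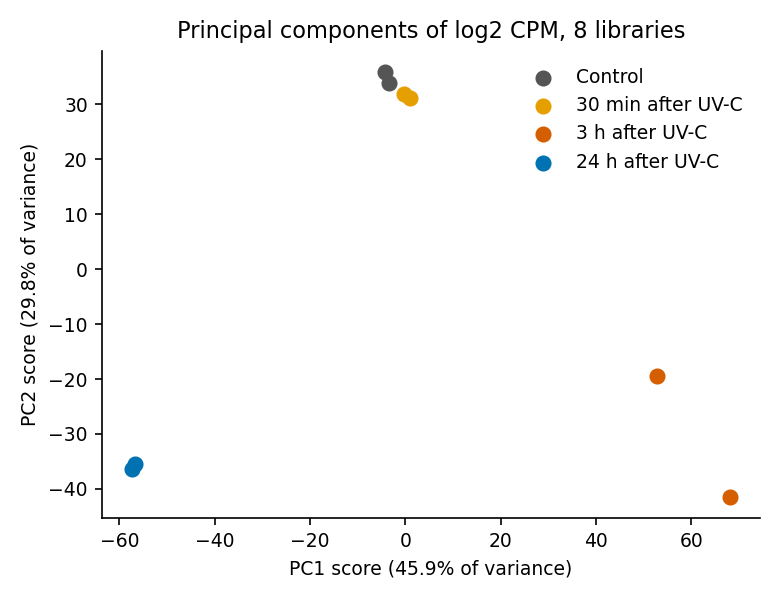
Principal components of log2 CPM in the 8 libraries, with 1 point per library and scores on the first (45.9% of variance) and second (29.8%) component on the axes. Control and 30 min libraries lie close together, and the 3 h and 24 h pairs lie apart from them and from each other.

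At 30 min the question was which transcripts respond first. FOS, a subunit of the AP-1 transcription factor, rose from 2.77 ± 0.416 to 35.9 ± 4.52 CPM (SD, n = 2), a log2 fold change of 3.69 (SE 0.196, adjusted p = 4.94e-05). EGR1, a zinc finger transcription factor of the immediate early response, rose from 57.8 ± 6 to 565.5 ± 42.4 CPM (log2 fold change 3.29, SE 0.27, adjusted p = 0.00114). JUNB (1.31), another AP-1 subunit, IER3 (1.28), an early response gene that limits apoptosis, DUSP1 (1.15), a phosphatase that inactivates MAP kinases, CTGF (0.93), a secreted matricellular protein, and GADD45A (0.85), a stress response gene and p53 target, also rose on the log2 scale. SMAD7, an inhibitor of TGF-beta signalling, fell from 28.7 ± 2.37 to 11.1 ± 0.683 CPM (log2 fold change -1.37, SE 0.151, adjusted p = 0.00886). FOS (ENSG00000170345) lies on chromosome 14 at 75278774 to 75282230 of GRCh38, EGR1 (ENSG00000120738) on chromosome 5 at 138465490 to 138469315, and SMAD7 (ENSG00000101665) on chromosome 18 at 48919853 to 48952052.

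Of the 15113 genes tested, 9 changed at 30 min, 8 higher and 1 lower, and 516 had an unadjusted p below 0.05. The call not named above was IKBKGP1, an unprocessed pseudogene that the naming rule left out and that is given here after its value was seen (log2 fold change 4.26, SE 0.484). In a fit without both 3 h libraries, chosen after the data were seen, the adjusted p was 3.99e-26 for EGR1, 2.72e-15 for IER3 and 1.35e-13 for CTGF. It was 1.11e-12 for JUNB and DUSP1, 1.56e-11 for GADD45A and 6.21e-10 for SMAD7. That fit called 224 genes, 52 higher and 172 lower, and DESeq2 on all libraries called 20, 12 higher and 8 lower. The count was 1 without Control replicate 1, Control replicate 2 or 30 min replicate 2, 5 without 30 min replicate 1, and 236 and 221 without 3 h replicate 1 or 2. FOS kept its call whichever library was left out. The call of EGR1 was lost without Control replicate 1 (adjusted p = 0.0524), Control replicate 2 (0.0777) or 30 min replicate 2 (0.0581), and that of IER3 without the same libraries (0.0715, 0.0881 and 0.0618). The calls of DUSP1, CTGF, GADD45A and SMAD7 were each lost without any 1 of the 4 Control and 30 min libraries, as was that of JUNB, which was lost also without either 24 h library and with total-count scaling (adjusted p = 0.198). The GADD45A call was lost without either 24 h library as well (0.092 and 0.0825).

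Immediate early genes were the list that moved most at 30 min: 6 of 30 tested members rose, none fell, and 15 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 0.30 (camera adjusted p = 1.87e-59, and adjusted p = 0.00506 with an estimated correlation). Ribosomal protein genes had a median of 0.11 with none of 55 called, such as RPL15 at 0.17 and RPS27 at 0.20, and the list passed with the preset (adjusted p = 4.36e-06). It had an adjusted p = 0.626 with an estimated correlation, 0.692 with fry and 0.319 without 30 min replicate 2. Inflammatory and NF-kB genes had a median of 0.12 with none of 22 called, such as IL6 at 0.42 and CCL2 at 0.57 (adjusted p = 0.0467, and adjusted p = 0.426 with an estimated correlation). That call was also lost without Control replicate 2 (0.101), 30 min replicate 1 or 2 (0.0785 and 0.0805) or 3 h replicate 1 or 2 (0.0962 and 0.106), and with fry (0.189) and the GC trend of each library removed (0.083). None of the remaining 18 tested lists passed at 30 min, and of their members only GADD45A among the p53 targets was called. Heat shock and chaperone genes (median 0.09, adjusted p = 0.0645) passed without both 3 h libraries (0.00234), with no count filter (0.0186), with the GC trend removed (0.0228), and without Control replicate 1 (0.0358), 30 min replicate 1 (0.013) or 3 h replicate 1 or 2 (0.00181 and 0.00182). The G2/M list passed without Control replicate 2 (0.018, median 0.11 against 0.05) and with the GC trend removed (0.0486). With no count filter the histone list (0.0186) and the repair list (0.048) passed. Without 30 min replicate 1 chromatin modifiers (0.0114) and mitochondrial mRNAs (0.0224) passed, the latter with a median of -0.12 against 0.00. The call counts adjusted over the list alone were the same in these lists. With total-count scaling the medians of p53 targets, interferon-stimulated genes, extracellular matrix genes, matrix proteases, RNA polymerase II factors and mitochondrial mRNAs changed sign at 30 min. The median had another sign than the mean or the test for DNA damage signalling, matrix proteases, mitochondrial mRNAs and epithelial markers.

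**Figure D2:**
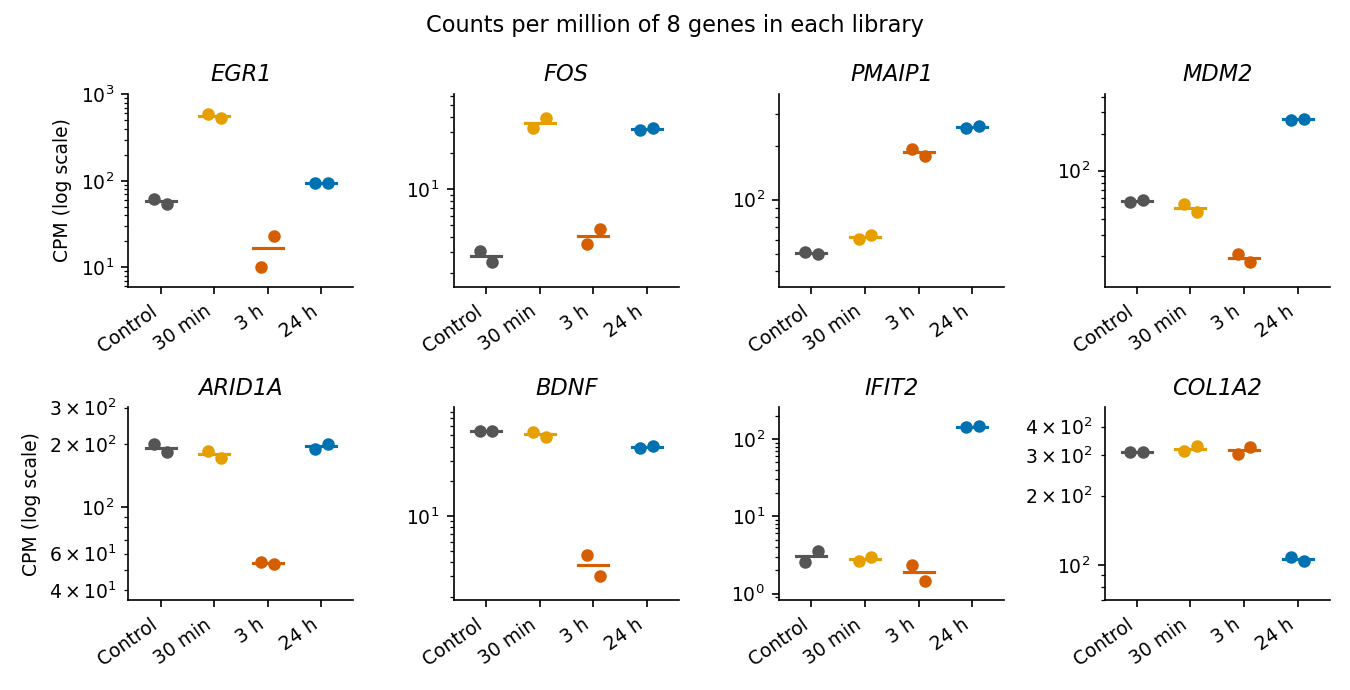
Levels in CPM on a log axis for 8 genes in each of the 8 libraries, with 1 point per library and a bar at the mean of each group. FOS rose to a mean of 35.9 at 30 min and 31.6 at 24 h from 2.77 in Control, ARID1A fell to 54.0 at 3 h from 193 in Control, and IFIT2 rose to 144 at 24 h from 3.03 in Control.

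At 3 h the question was how expression differed from Control after several hours of recovery. PMAIP1, a pro-apoptotic BCL2 family member, rose from 50.6 ± 1.22 to 183 ± 11.4 CPM (SD, n = 2; log2 fold change 1.86, SE 0.103, adjusted p = 1.88e-06). ID2 (2.11), an inhibitor of basic helix-loop-helix factors, and SAT1 (1.57), an enzyme of polyamine breakdown, rose as well, as did MINOS1 (1.57). MAGED4 (3.95) and RFPL4A (1.96) were also among the largest rises, but both have near-identical copies in the genome, so that their counts cannot be assigned with certainty. ZNRF3, a ubiquitin ligase that limits WNT signalling, fell from 15.1 ± 0.0891 to 0.984 ± 0.2 CPM (log2 fold change -3.93, SE 0.223, adjusted p = 2.02e-06). BDNF, a neurotrophin, fell from 54.2 ± 0.259 to 3.79 ± 1.1 CPM (log2 fold change -3.84, SE 0.181, adjusted p = 1.49e-06), and FBXO34 (-3.75), CCDC12 (-3.43), HAS2 (-3.40), which makes hyaluronan, and BMT2 (-3.37) fell with it.

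At 3 h 5570 genes changed, 2438 higher and 3132 lower, and of those that moved at least 2-fold 344 were higher and 1549 lower. Scaling by total counts moved the median log2 fold change of all genes from -0.02 to -0.23 and the split to 1249 higher and 4314 lower, so that directions at this time are relative to the median gene. The count was 3337 when only Control and 3 h were fitted, 3015 without Control replicate 1, 3164 without Control replicate 2, and 8783 without 3 h replicate 2.

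Genes for chromatin modifiers and remodellers fell at 3 h: of 75 tested members 45 were lower and 5 higher, or 48 and 7 when adjusted over the list alone. ARID1A, a subunit of the SWI/SNF remodelling complex, fell by 1.84 on the log2 scale (SE 0.106), from 193 ± 12.6 to 54.0 ± 0.698 CPM. KAT6A, a histone acetyltransferase, SETD1B, a histone H3 lysine methyltransferase, and TET2, an enzyme that oxidises 5-methylcytosine, had log2 fold changes of -2.52, -2.08 and -2.79. The list median was -0.71 (camera adjusted p = 5.62e-12, and adjusted p = 0.341 with an estimated correlation). Ribosomal protein genes rose, with 49 of 55 higher and none lower (51 and none when adjusted over the list alone) and a median of 0.67. Examples were RPL6 (0.91), RPL32 (0.70), RPS24 (0.79) and RPS27 (0.93), and the list had an adjusted p = 2.77e-16 with the preset and an adjusted p = 0.341 with an estimated correlation.

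Of 27 extracellular matrix genes 10 were higher and none lower at 3 h (13 and none when adjusted over the list alone). The higher genes included FN1 (0.77), which encodes fibronectin, SPARC (0.49), LUM (0.92) and LOX (0.59), which crosslinks collagen. The list median was 0.32 (adjusted p = 0.00758, and adjusted p = 0.341 with an estimated correlation). Matrix proteases and inhibitors had 10 members higher and 2 lower of 21, also when adjusted over the list alone. CTSB (0.66), TIMP1 (0.74) and CTSL (0.64) were higher and ADAMTS5 (-1.24) lower. That list had a median of 0.43 and an adjusted p = 0.0459 (adjusted p = 0.541 with an estimated correlation), and the call was lost with total-count scaling, with the GC trend removed and without any 1 library except 3 h replicate 2. Heat shock and chaperone genes had 10 higher and 3 lower of 20, also when adjusted over the list alone. HSP90AA1 (0.92) and HSPA8 (0.85), cytosolic chaperones, rose, and the median was 0.39 (adjusted p = 0.0216, and adjusted p = 0.499 with an estimated correlation). Replication-dependent histone genes had 7 of 22 higher and none lower, also when adjusted over the list alone. HIST1H3B (2.87) and HIST2H2BE (1.14) were examples, and the median was 0.46 (adjusted p = 0.00568, and adjusted p = 0.341 with an estimated correlation). Most mRNAs of this list lack poly(A) tails, and other RNAs without such tails went both ways at 3 h. MT-RNR2 (2.93) and both genes named RNA5-8SN2 (5.92 and 3.99), a ribosomal RNA, were higher. The RNA5-8SN2 genes were at 10.1 ± 11.5 and 0.526 ± 0.277 CPM. In Control they were at 0.162 and 0.0264 CPM, near or under the limit that a count of 0 allows. Of the mitochondrial transfer RNAs, MT-TN (2.29) and MT-TC (2.39) were among the higher, at 78.0 and 35.9 CPM. MT-TH (-2.12, adjusted p = 0.00436) and MT-TG (-2.01, 0.0449) were lower but scarce. MT-TH went from 1.95 CPM in Control to 0.439, and MT-TG from 0.778 to 0.184, near the limit that a count of 0 allows. RN7SL2 had -2.04 and was not called (0.056). Mitochondrially encoded mRNAs had 8 of 13 higher and none lower, also when adjusted over the list alone. MT-CO1 (1.16) and MT-CO2 (0.95), subunits of cytochrome c oxidase, were among them, and the median was 0.64 (adjusted p = 0.00346, and adjusted p = 0.541 with an estimated correlation). Mitochondrial ribosomal RNA was higher at the same time, with a log2 fold change of 2.93 for MT-RNR2. Without 3 h replicate 2 the histone list had an adjusted p of 0.0917 and the mitochondrial mRNAs one of 0.167, and the latter had 0.131 with fry.

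The other lists did not pass at 3 h. Of 52 nucleotide excision repair genes 17 were higher and 7 lower, also when adjusted over the list alone, with a median of 0.12 that became -0.09 with total-count scaling (adjusted p = 0.144). CETN2 (1.01), a partner of XPC in damage recognition, was higher, while ERCC6 (-0.97), which acts at stalled RNA polymerase II, CDK7 (-1.20), a kinase of TFIIH, and ERCC4 (-0.94), part of the nuclease that cuts 5' of the lesion, were lower. Of 33 p53 targets 4 were higher and 11 lower, also when adjusted over the list alone. PMAIP1 (1.86) was higher and MDM2 (-1.56), the ubiquitin ligase of p53, PPM1D (-2.37) and PLK2 (-1.44) were lower (median -0.14, adjusted p = 0.162). The list passed with no count filter (0.0317) and with fry (9.77e-05). Of 30 immediate early genes 6 were higher and 15 lower, or 7 and 15 when adjusted over the list alone. CTGF (1.24) was higher and CYR61 (-1.77), KLF6 (-1.38) and KLF2 (-1.57) were lower (median -0.46, adjusted p = 0.126). This list passed with no count filter (0.0317), with fry (0.0145) and without 3 h replicate 2 (0.00142). Cholesterol synthesis genes had 2 higher and 7 lower of 23, also when adjusted over the list alone. HMGCS1 (-1.38), an early enzyme of the pathway, was lower (median -0.20, adjusted p = 0.0602, and adjusted p = 0.341 with an estimated correlation). The list passed with total-count scaling (0.0226), the GC trend removed (0.0273), no count filter (0.0196) and fry (0.000504). It passed also without Control replicate 2 (0.0498), 3 h replicate 1 (0.00976) or 3 h replicate 2 (0.00679). RNA polymerase II and elongation factors had 9 higher and 10 lower of 39, or 9 and 12 when adjusted over the list alone. ELL2 (-2.00) and ELL (-2.29), which speed elongation, were lower. The list median was 0.01, and -0.20 with total-count scaling, while its mean was -0.21 and its test pointed down (adjusted p = 0.42, and 0.00129 with fry).

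DNA replication and G1/S genes had 13 higher and 8 lower of 38, with CDC25A (-2.12), a phosphatase that drives entry into S phase, lower (adjusted p = 0.78). The G2/M list had 3 higher and 6 lower of 32, with CENPA (-1.71), the centromeric histone, lower (adjusted p = 0.668), and the DNA damage signalling list had 3 higher and 7 lower of 35, with RNF168 (-1.52) lower (adjusted p = 0.941). These 3 lists had the same counts when adjusted over the list alone, and the median of each was of opposite sign to its mean or its test. With total-count scaling the replication median turned from 0.08 to -0.13 and the G2/M median from 0.09 to -0.12. The stress response list had 4 higher and 10 lower of 25 (5 and 11 when adjusted over the list alone), with XBP1 (1.10) higher and DDIT4 (-2.96) lower (adjusted p = 0.668, and 0.00848 with fry). Inflammatory genes had 4 higher and 5 lower of 22, also when adjusted over the list alone, with PTGS2 (2.32) higher and BIRC3 (-2.24) and NFKB1 (-1.41) lower. Their median was 0.30 and their mean 0.15 (adjusted p = 0.668), and the call of PTGS2 was lost without Control replicate 1 (0.0747). Interferon-stimulated genes had 5 higher and 2 lower of 36 but none when adjusted over the list alone, with IFIT3 (-0.71) lower (median 0.17, or -0.03 with total-count scaling, mean -0.04, adjusted p = 0.229). The IFIT3 call at 3 h was lost without any 1 library except 3 h replicate 1. Among markers of other cell types, smooth muscle and myofibroblast markers had 4 higher and 1 lower of 11 (5 and 1 when adjusted over the list alone; TPM1 0.67, adjusted p = 0.0632), epithelial markers 3 higher and 1 lower of 7 both ways (KRT18 0.43; median 0.30, mean -0.16, adjusted p = 0.42), and endothelial markers none of 7 (adjusted p = 0.919). The smooth muscle list passed with no count filter (0.0248), with the GC trend removed (0.0472), with fry (0.00809) and without 3 h replicate 1 (0.0191). With total-count scaling the calls of TAGLN and CNN1 among its 4 higher members were lost, with 0.24 (adjusted p = 0.0644) and 0.29 (0.179). TAGLN also lost its call without either Control library, and CNN1 without Control replicate 1 or 30 min replicate 1. With total-count scaling the calls of the 3 higher epithelial markers were lost, with 0.22 for KRT18 (adjusted p = 0.0666), 0.22 for KRT17 (0.233) and 0.16 for KRT8 (0.385). Those calls were also each lost without either Control library, those of KRT17 and KRT8 without either 24 h library, and that of KRT8 without either 30 min library. Neither of the 2 tested leukocyte markers, CD14 (0.04) and CSF1R (-1.06), was called.

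**Figure D3:**
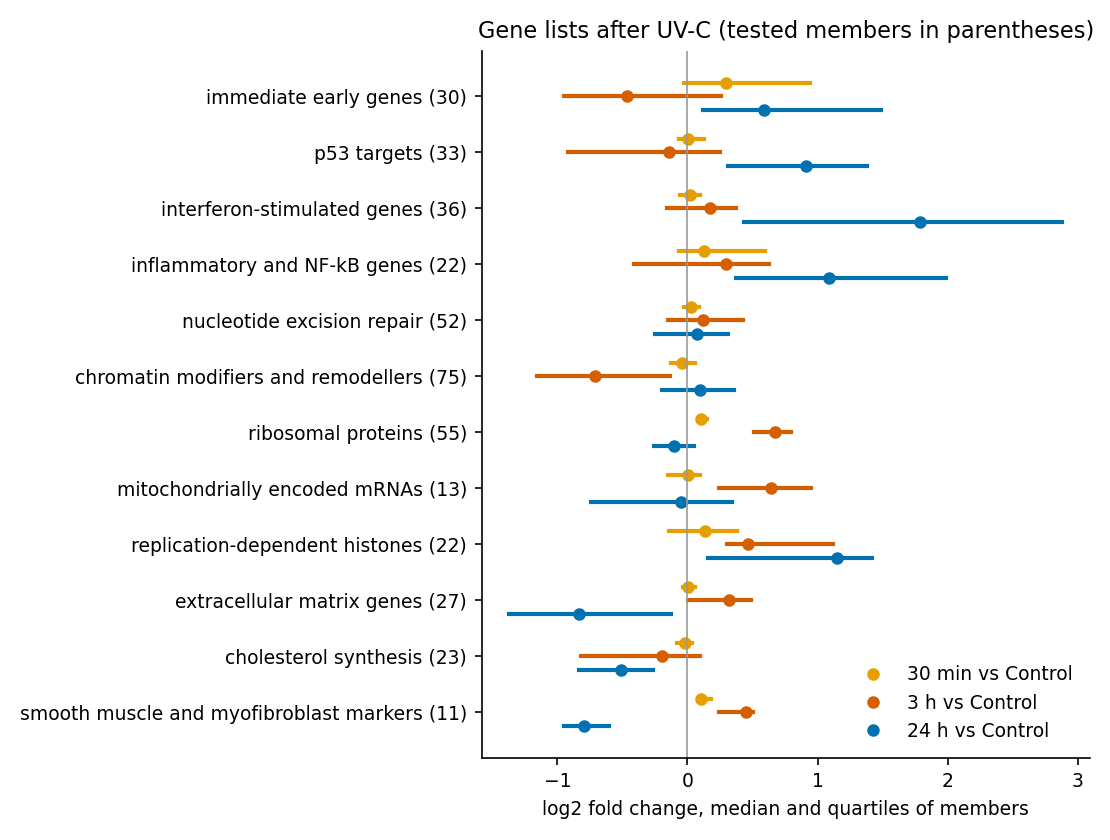
Median (point) and quartiles (line) of the log2 fold change against Control over the tested members of 12 gene lists at 30 min, 3 h and 24 h. Chromatin genes had a median of -0.71 and ribosomal protein genes 0.67 at 3 h, and interferon-stimulated genes had a median of 1.79 and extracellular matrix genes -0.83 at 24 h.

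At 24 h the question was which changes were present a day after UV-C. The largest rises were in interferon-stimulated genes: IFIT2, which inhibits translation of foreign RNA, rose from 3.03 ± 0.696 to 144 ± 4.13 CPM (SD, n = 2; log2 fold change 5.58, SE 0.201, adjusted p = 1.07e-06). OASL rose from 0.296 ± 0.0296 to 20 ± 0.311 CPM (log2 fold change 6.05, SE 0.517), and IFIT3 (4.93), IFI44 (4.27) and DDX60 (3.93) rose with them. FOS was again high, at 31.6 ± 0.737 CPM (log2 fold change 3.51, SE 0.196, adjusted p = 4.99e-06). The largest falls were in genes of long span: SEMA5A, an axon guidance gene of 511 kb on chromosome 5 (9035026 to 9546075), fell from 80.8 ± 0.232 to 9.15 ± 0.382 CPM (log2 fold change -3.14, SE 0.165, adjusted p = 4.99e-06). CAMK1D (-3.43, 486 kb), ANKRD44 (-3.29, 344 kb), CDH12 (-3.16, 1103 kb), a cadherin, TENM4 (-3.05, 788 kb) and MAP2 (-2.91, 310 kb), a microtubule-associated protein gene, fell as well.

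At 24 h 4449 genes changed, 2048 higher and 2401 lower, of which 659 and 948 by at least 2-fold. Scaling by total counts gave 2958 higher and 2046 lower, with a median of 0.08 over all genes. The count was 1848 and 1986 without Control replicate 1 or 2, 2012 and 1870 without 24 h replicate 1 or 2, and 8321 and 8297 without 3 h replicate 1 or 2. It was 8262 without both 3 h libraries, an alternative chosen after the data were seen, and 8678 when only Control and 24 h were fitted.

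Of 36 interferon-stimulated genes 27 rose and none fell at 24 h, also when adjusted over the list alone, with a median of 1.79 (camera adjusted p = 2.74e-32, and adjusted p = 0.00637 with an estimated correlation). DDX58 (3.51), which encodes the RNA sensor RIG-I, and HERC5 (3.22), the ligase for ISG15, were among them. Of 33 p53 targets 23 rose and 2 fell, or 26 and 2 when adjusted over the list alone. MDM2 rose from 56.9 ± 1.52 to 265 ± 4.31 CPM (log2 fold change 2.22, SE 0.119), and PMAIP1 (2.33), BTG2 (3.16), an antiproliferative gene, and GADD45A (1.47) rose too, as did CDKN1A (1.37), the cyclin-dependent kinase inhibitor p21, named after its value was seen. The list median was 0.91 (adjusted p = 5.36e-18, and adjusted p = 0.00637 with an estimated correlation). Immediate early genes had 15 higher and 3 lower of 30 (18 and 4 when adjusted over the list alone) and a median of 0.59, with ATF3 (2.38) and FOSB (3.16) as examples (adjusted p = 3.67e-10, and adjusted p = 0.0284 with an estimated correlation). Inflammatory and NF-kB genes had 14 higher and none lower of 22 (15 and 1 when adjusted over the list alone) and a median of 1.09. NFKB2 (1.13), BIRC3 (2.55), TNFAIP3 (2.39), a feedback inhibitor of NF-kB, and the cytokine gene IL6 (1.29) were examples (adjusted p = 1.77e-07, and adjusted p = 0.0267 with an estimated correlation).

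Extracellular matrix genes fell at 24 h, with 16 of 27 lower and 1 higher, or 17 and 1 when adjusted over the list alone, and a median of -0.83 (adjusted p = 1.63e-12, and adjusted p = 0.0284 with an estimated correlation). COL1A2 fell from 310 ± 0.367 to 106 ± 3.07 CPM (log2 fold change -1.55, SE 0.0958), and the collagen genes COL3A1 (-1.16) and COL5A2 (-1.13) and the fibrillin gene FBN2 (-1.65) fell with it. Cholesterol synthesis genes fell, with 12 of 23 lower and none higher, or 17 and none when adjusted over the list alone, and a median of -0.51 (adjusted p = 1.69e-05, and adjusted p = 0.0284 with an estimated correlation). INSIG1 (-1.26), LSS (-1.18), which makes lanosterol, and SREBF2 (-0.83), the transcription factor of the pathway, were among them. Smooth muscle and myofibroblast markers had 7 lower and 1 higher of 11, also when adjusted over the list alone. TAGLN (-0.96) and TPM2 (-0.89) were lower, and the median was -0.80 (adjusted p = 0.00048, and adjusted p = 0.0675 with an estimated correlation). Replication-dependent histone genes had 10 higher and 2 lower of 22 (13 and 2 when adjusted over the list alone). HIST1H2BK (1.29) and HIST1H3B (3.56) were higher, and the median was 1.15 (adjusted p = 0.000102, and adjusted p = 0.0675 with an estimated correlation). Among other RNAs without poly(A) tails, MT-RNR2 (4.25) and both RNA5-8SN2 genes (5.09 and 4.09) were higher at 24 h, and 16 small structural RNAs had a median of 0.62. MT-TH (-3.84), a mitochondrial transfer RNA, was lower, at 0.129 CPM, under the limit that a count of 0 allows. RNA polymerase II and elongation factors had 12 higher and 2 lower of 39 (13 and 2 when adjusted over the list alone). POLR2A (1.06), the largest subunit, and HEXIM1 (0.95), an inhibitor of P-TEFb, were higher, and the median was 0.17 (adjusted p = 0.00497, and adjusted p = 0.0731 with an estimated correlation). DNA damage signalling genes had 5 higher and none lower of 35 (4 and none when adjusted over the list alone). RNF8 (0.93) and HUS1 (0.97) were higher, and the median was 0.18 (adjusted p = 0.0415, and adjusted p = 0.742 with an estimated correlation). Without Control replicate 1, 30 min replicate 1, 30 min replicate 2 or 24 h replicate 2 this call was lost, with adjusted p values of 0.0969, 0.0511, 0.0552 and 0.0596, and it was lost with the GC trend removed (0.0595) and with fry (0.0878).

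Nucleotide excision repair genes did not shift as a list at 24 h, with 9 higher and 6 lower of 52, also when adjusted over the list alone (median 0.07, adjusted p = 0.617). XPC (0.49), which recognises distorted DNA, and XAB2 (0.67), which acts in transcription-coupled repair, were higher, and ERCC1 (-0.51), partner of ERCC4, and POLE4 (-0.79) were lower. DDB2 (0.64), which detects UV photoproducts, was also higher and is named after its value was seen. The calls of XPC, ERCC1 and MKI67, a proliferation marker of the G2/M list, were each lost without any 1 of the 4 Control and 24 h libraries, and that of XAB2 without Control replicate 2. Chromatin modifiers and remodellers had 17 higher and 14 lower of 75 (18 and 15 when adjusted over the list alone). KAT7 (0.60) was higher and HDAC4 (-2.25), KDM4C (-1.58) and ARID1B (-1.37) were lower (median 0.09, mean -0.01, adjusted p = 0.774). DNA replication and G1/S genes had 7 higher and 12 lower of 38 (10 and 15 when adjusted over the list alone), with E2F8 (1.36) higher and MCM6 (-0.79), part of the replicative helicase, lower (median -0.06, or 0.02 with total-count scaling, adjusted p = 0.779). The G2/M list had 5 higher and 4 lower of 32, also when adjusted over the list alone, with MKI67 (0.48) higher and CCNB1 (-0.65), cyclin B1, lower (adjusted p = 0.779).

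Matrix proteases and inhibitors had 4 higher and 7 lower of 21 at 24 h (4 and 8 when adjusted over the list alone), with SERPINB2 (2.09), a plasminogen activator inhibitor, higher and PLAU (-1.06), a plasminogen activator, lower (median -0.05, or 0.03 with total-count scaling, adjusted p = 0.225). The stress response list had 5 higher and 8 lower of 25 (5 and 9 when adjusted over the list alone), with the amino acid transporter genes SLC3A2 (1.72) higher and SLC7A5 (-1.19) lower (adjusted p = 0.779). Heat shock and chaperone genes had 1 higher and 8 lower of 20 (2 and 9 when adjusted over the list alone), with HSPE1 (-1.30) lower (adjusted p = 0.118). That list passed without both 3 h libraries (0.0206), without 3 h replicate 1 or 2 (0.0121 and 0.0125), with no count filter (0.0117) and with fry (0.0394). Ribosomal protein genes had 6 higher and 8 lower of 55 both ways (adjusted p = 0.619), with RPS24 (0.44) higher and RPS3 (-0.52) lower. The RPS24 call was lost without any 1 of the 4 Control and 24 h libraries (adjusted p from 0.0588 to 0.0893). Mitochondrially encoded mRNAs had 3 higher and 4 lower of 13 both ways (median -0.05, or 0.03 with total-count scaling, adjusted p = 0.966), with MT-CO1 (0.60) higher and MT-CYB (-1.15) lower, while the ribosomal RNAs MT-RNR2 (4.25) and MT-RNR1 (3.69) rose. The MT-CYB call was lost without 24 h replicate 2 (adjusted p = 0.0548). Epithelial markers had none of 7 called (adjusted p = 0.619), and endothelial markers had ROBO4 (0.62) higher and TEK (-1.57) lower of 7 both ways (adjusted p = 0.876). The ROBO4 call was lost with the DESeq2 Wald test (0.0635) and without any 1 Control, 30 min or 24 h library (0.0511 to 0.185), and that of TEK without Control replicate 2 (0.114) or 24 h replicate 1 (0.107). Of the 2 tested leukocyte markers CD14, a co-receptor for lipopolysaccharide, rose from 1.13 ± 0.109 to 7.13 ± 0.428 CPM (log2 fold change 2.65, SE 0.279), and CSF1R (0.09) was not called.

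UV photoproducts block RNA polymerase II, so that the expected number of lesions in a gene grows with its span, and the genes were compared by span. At 24 h the median log2 fold change of 2523 protein-coding genes of at least 100 kb was -0.45, against 0.02 for 2339 genes of at most 10 kb, a difference of -0.47. Of the long genes 1143 fell and 140 rose, and of the short genes 257 fell and 351 rose. Among 993 genes of more than 200 kb 667 fell and 17 rose, with a median of -0.95. The long genes shifted against all other genes with the preset (camera p = 3.69e-24), and had p = 0.0749 with an estimated correlation. The difference was -0.46 and -0.45 in the 24 h replicates taken singly. With limits of 50 kb and 20 kb it was -0.23.

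At 3 h the long genes differed from the short ones by -0.20 (camera p = 0.000499, and p = 0.462 with an estimated correlation), with 805 of the long genes lower and 350 higher. The difference was 0.06 in 3 h replicate 1 and -0.45 in 3 h replicate 2. Without 3 h replicate 2 the sign turned, with 0.06 over the genes that passed the filter of that fit, and without 3 h replicate 1 the difference was -0.47. Within 3 bins of transcript length, from the shortest to the longest transcripts, the 3 h difference was 0.05, -0.06 and -0.04, and within 3 bins of transcript GC content it was -0.31, -0.42 and -0.33. It was -0.09 without a count filter and -0.30 with the GC trend of each library removed. At 30 min the difference was -0.09 (p = 0.0196, and p = 0.61 with an estimated correlation), with p = 0.147 without a count filter and 0.158 without Control replicate 2. Within the bins of transcript length it was -0.03, -0.03 and -0.05. It was -0.16 without 30 min replicate 1. Without 30 min replicate 2 it was -0.01, with a camera p of 0.892.

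**Figure D4:**
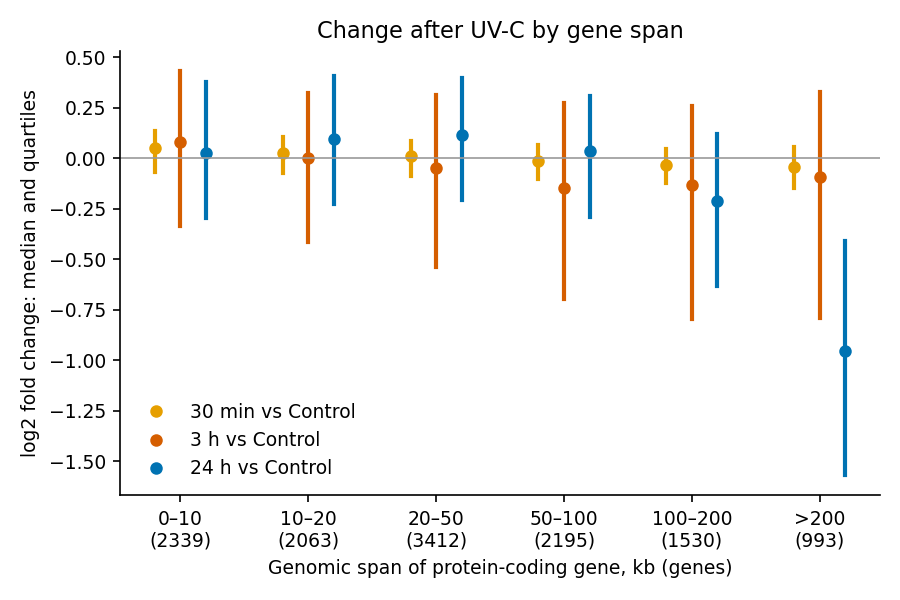
Median (point) and quartiles (line) of the log2 fold change against Control for protein-coding genes binned by genomic span in kb, at 30 min, 3 h and 24 h, with the number of genes below each bin. Genes of more than 200 kb had a median of -0.95 at 24 h, and those of 100 to 200 kb one of -0.21.

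Between 30 min and 3 h, EGR1 fell from 565.5 ± 42.4 to 16.6 ± 9.13 CPM (SD, n = 2; log2 fold change -5.08, SE 0.299, adjusted p = 4.17e-06), below its Control level. ZNRF3 (-3.92) and BDNF (-3.77) fell as well, and ID2 (1.85), TMPPE (1.85) and NPIPB4 (1.82), a member of a family with near-identical copies, rose. Immediate early genes had 20 members lower and 4 higher of 30, or 21 and 5 when adjusted over the list alone, with a median of -0.89 (adjusted p = 4.02e-10, and adjusted p = 0.135 with an estimated correlation). Chromatin genes had 44 lower and 4 higher of 75 (46 and 6 when adjusted over the list alone; adjusted p = 5.86e-12, and adjusted p = 0.274 with an estimated correlation), and ribosomal protein genes had 44 higher and none lower of 55 (47 and none when adjusted over the list alone; adjusted p = 5.68e-13, and adjusted p = 0.298 with an estimated correlation). In all 5102 genes differed, 2158 higher and 2944 lower at 3 h, and with total-count scaling 1123 were higher and 3908 lower, with a median of -0.19 over all genes. The count was 2517 and 2698 without 30 min replicate 1 or 2, 8537 without 3 h replicate 2, and 2693 when only these 2 groups were fitted.

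Between 3 h and 24 h, IFIT2 rose from 1.88 ± 0.617 to 144 ± 4.13 CPM (log2 fold change 6.27, SE 0.216) and IFIT3 from 4.05 ± 1.57 to 202 ± 4.59 CPM (log2 fold change 5.65, SE 0.215). OASL was at 0.0602 ± 0.0851 CPM at 3 h, under the limit that a count of 0 allows, and at 20 ± 0.311 CPM at 24 h. CDH12 (-3.68) and KLHL4 (-3.19) fell, as did MAGED4, which has a near-identical copy (-6.10, SE 1.09). The p53 targets had 25 higher and 3 lower of 33 (26 and 3 when adjusted over the list alone) and a median of 1.15 (adjusted p = 5.75e-12, and adjusted p = 0.0249 with an estimated correlation). Immediate early genes had 23 higher and 1 lower of 30 (24 and 1 when adjusted over the list alone) and a median of 1.27 (adjusted p = 8.62e-09), and interferon-stimulated genes 24 higher and 1 lower of 36 both ways and a median of 1.67 (adjusted p = 1.54e-11). Extracellular matrix genes had 21 lower and none higher of 27 both ways and a median of -1.11 (adjusted p = 2.18e-12), and these last 3 lists each had an adjusted p = 0.0479 with an estimated correlation. In all 7624 genes differed, 4014 higher and 3610 lower at 24 h, and with total-count scaling 5616 were higher and 2118 lower, with a median of 0.30 over all genes.

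Genes called at both 3 h and 24 h numbered 1987, of which 452 were higher at both times, 608 lower at both, 553 lower and then higher, and 374 higher and then lower. Lists drawn independently of each other would share 1640 genes, with 330.4, 497.6, 424.4 and 387.3 in these classes. Both comparisons used the same 2 Control libraries, which cannot be divided since each part would hold 1 library, so part of the excess of genes moving the same way may come from the shared controls. In 30 simulated sets of unchanged groups sharing their controls, the overlap averaged 0.1 genes and was at most 1. Those sets hold no changed genes, so that a low overlap was fixed in advance. It cannot show how many of the 1987 genes owe a call to the shared controls. The covariance of the fold changes across genes was 0.158, against 0.0458 in the simulated sets, and their correlation was 0.225 against 0.496. Unchanged groups sharing their controls correlate by construction, so that the simulated correlation was fixed in advance and sets no measure for 0.225. All simulated groups took the same dispersion for each gene, which includes the spread between the 3 h replicates. The simulated covariance therefore need not match the part that the shared controls add. Genes are not independent replicates. The overlap was 498 and 567 genes without Control replicate 1 or 2, 779 and 728 without 24 h replicate 1 or 2, and 4624 and 5428 without 3 h replicate 1 or 2. It was 3625 when the GC trend of each library was removed, an alternative chosen after the data were seen.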

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

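The test of the mitochondrial mRNAs, the fits without both 3 h libraries and the fits with the GC trend of each library removed were chosen only after the results they bear on were seen.

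Effects of UV-C differed between times by the test of the difference itself. Between 3 h and 30 min 5102 genes differed, and between 24 h and 3 h 7624. Of the genes called at both later times, 553 were lower at 3 h and higher at 24 h and 374 were higher and then lower. The difference between the times passed in each, which calls of opposite sign against the same Control make almost certain beforehand. Against 3 h, the median log2 fold change at 24 h was 1.15 for p53 targets, 1.27 for immediate early genes, 1.67 for interferon-stimulated genes and -1.11 for extracellular matrix genes. Of the named genes 40 were called in opposite directions at 3 h and 24 h.

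EGR1 differed by -5.08 on the log2 scale between 3 h and 30 min, with 3.29 at 30 min and -1.79 at 3 h against Control. DUSP1 differed by -1.93 between these times, with 1.15 at 30 min and -0.79 at 3 h. IER3 differed by -1.66 between 3 h and 30 min and by 0.89 between 24 h and 3 h, with 1.28, -0.37 and 0.52 at the 3 times. CDH12 differed by -3.68 between 24 h and 3 h, with 0.53 at 3 h (adjusted p = 0.0427) and -3.16 at 24 h. IFIT3 differed by 5.65 between 24 h and 3 h, with -0.71 at 3 h and 4.93 at 24 h. The call of IFIT3 at 3 h was lost without any 1 library except 3 h replicate 1, with adjusted p values of 0.069 and 0.163 without Control replicate 1 or 2, 0.0554 and 0.0577 without 30 min replicate 1 or 2, 0.107 without 3 h replicate 2, and 0.0532 and 0.054 without 24 h replicate 1 or 2.

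Genes of long span were lower at 24 h, by -0.47 against short genes. GC content does not account for this, since within 3 bins of transcript GC content the difference closest to 0 was -0.427, and neither does transcript length, with -0.412 as the closest to 0 within 3 bins of exonic length. The difference was -0.53 when the GC trend of each library was removed, and -0.235 with span limits of 50 kb and 20 kb. What stays open is a biological hypothesis, that blocked transcription may deplete long genes, which these data cannot separate from other properties of long genes. The medians did not fall evenly with span: they were 0.0247 up to 10 kb, 0.0981 from 10 to 20 kb, 0.114 from 20 to 50 kb and 0.0369 from 50 to 100 kb. They were -0.209 from 100 to 200 kb and -0.953 above 200 kb. The call passed with the preset correlation and had p = 0.0749 with an estimated one.

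The 3 h replicates differed more than those of any other group. Transcript GC content explained 56.4% of the variance of their log2 difference, against 8.72% in Control, 0.951% at 30 min and 0.166% at 24 h, which is consistent with a GC-dependent step in library preparation or sequencing. Transcript length explained 3.51% at 3 h, which argues against a length bias between these replicates. It explained 13% between the 30 min replicates, against 0.342% in Control and 0.0372% at 24 h. The ribosomal protein and span results at 30 min were lost without 30 min replicate 2, and a part of transcript length in this was not tested. A different extent of one UV response explained 10.8%, between the bounds set for it, so that it cannot be told apart from other sources for the part that GC content leaves. The labels give no batch for these libraries.

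Mitochondrial ribosomal RNA was higher at 24 h, with a log2 fold change of 4.25 (SE 0.165) for MT-RNR2 and 3.69 (SE 0.318) for MT-RNR1. The 13 mitochondrial mRNAs did not rise as a set, with a median of -0.0486 (bootstrap SE 0.264, 3 higher and 4 lower). The value 2 SE above the median was 0.479, against a bound of 0.5 set for a rise of mitochondrial RNA of all kinds. That SE treats the mRNAs as independent, while their estimated correlation was 0.83, and it does not measure error between libraries. The bound therefore cannot decide on such a rise. With 1000 bootstrap draws 34 of 40 runs met that bound, and the number of draws was raised to 1e+05 after this was seen. More RNA without poly(A) tails in the libraries stays open and may contribute: 16 small structural RNAs had a median of 0.619 (bootstrap SE 0.258), between the bounds set for it, and most lay near the floor. RN7SL2, the most abundant of them, had -1.54 (adjusted p = 0.132). Other RNAs without poly(A) tails, looked at after their values were seen, went both ways. Both genes named RNA5-8SN2, a ribosomal RNA, were higher (5.09 and 4.09, adjusted p = 0.00708 and 0.0263). Their Control levels of 0.162 and 0.0264 CPM were near or under the limit that a count of 0 allows. Of 9 mitochondrial transfer RNAs 5 were higher, among them MT-TN (3.34), MT-TC (2.93) and MT-TP (2.92). MT-TH (-3.84) was lower, from 1.95 CPM in Control to 0.129, under the limit that a count of 0 allows. Replication-dependent histone mRNAs, most of which lack poly(A) tails, had a median of 1.15 with 10 higher and 2 lower of 22, so that their rise and that of the ribosomal RNAs may share this source. A change in mitochondrial ribosomal RNA itself was not tested.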

How the results depend on the processing

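The fits without both 3 h libraries and with the GC trend of each library removed were chosen after the data were seen, and all other alternatives were planned. With 2 libraries per group, a fit without 1 library of a group assumes that the remaining one varies like the other groups. The self-test recovered 13.4% of 1.5-fold changes in the set simulated for 30 min and 20.9% in that for 3 h, which limits small effects. Neither set held the wider spread between the 3 h replicates. DESeq2 size factors left all 12 main results within 1.5 times of their value or on the same side of the threshold, and so did total-count scaling for the 11 it was run on and limma on FPKM with either pseudocount for the 5 counts of genes. Beyond what the design fixes, the cause was not tested for the values below. A fold change of at least 2 and the fits on fewer libraries use fewer genes or samples by construction. A fit without 1 or both 3 h libraries also leaves out the spread between the 3 h replicates, which otherwise enters a dispersion shared by all groups. That spread had an SD of 0.49 log2 units, against 0.15 in Control, 0.18 at 30 min and 0.16 at 24 h.

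Genes changed at 30 min numbered 9, with 59 without a count filter, 20 with the DESeq2 Wald test, 282 when only the 2 groups were compared, 224 without both 3 h libraries and 14 with the GC trend removed. Leaving out 1 library gave 1 (without Control replicate 1, Control replicate 2 or 30 min replicate 2) to 236 (without 3 h replicate 1), with 221 without 3 h replicate 2 and 5 without 30 min replicate 1. Genes changed at 3 h numbered 5570, with 3337 when only the 2 groups were compared and 1893 at a fold change of at least 2. Leaving out 1 library gave 3015 (Control replicate 1) to 8783 (3 h replicate 2), with 3164 without Control replicate 2. Genes changed at 24 h numbered 4449, with 8262 without both 3 h libraries, 8678 when only the 2 groups were compared and 1607 at a fold change of at least 2. Leaving out 1 library gave 1848 (Control replicate 1) to 8321 (3 h replicate 1), with 1986 without Control replicate 2, 2012 and 1870 without 24 h replicate 1 or 2, and 8297 without 3 h replicate 2. Genes differing between 3 h and 30 min numbered 5102, with 2693 when only the 2 groups were compared, 1675 at a fold change of at least 2, and 2517 (without 30 min replicate 1) to 8537 (without 3 h replicate 2) with 1 library left out, where 30 min replicate 2 gave 2698. Genes differing between 24 h and 3 h numbered 7624, with 3460 at a fold change of at least 2 and 5328 to 9728 with 1 library left out. Genes changed at both 3 h and 24 h numbered 1987, with 3625 with the GC trend removed and 498 (without Control replicate 1) to 5428 (without 3 h replicate 2) with 1 library left out; without Control replicate 2, 3 h replicate 1, 24 h replicate 1 and 24 h replicate 2 they were 567, 4624, 779 and 728.

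At 30 min 3 lists passed, with 6 without a count filter, 1 with an estimated correlation, 1 with fry, and 1 (without 30 min replicate 2) to 5 (without 30 min replicate 1) with 1 library left out. At 3 h 7 lists passed, with 11 without a count filter, 0 with an estimated correlation and 12 with fry, and at 24 h 10, with 6 with an estimated correlation. The long-minus-short difference at 30 min was -0.0852, with -0.0521 (p = 0.147) without a count filter, p = 0.61 with an estimated correlation, and -0.164 (without 30 min replicate 1) to -0.0125 (without 30 min replicate 2, p = 0.892) with 1 library left out, where Control replicate 2 gave -0.0688 (p = 0.158). At 3 h it was -0.195, with p = 0.462 with an estimated correlation, -0.0903 without a count filter, -0.298 with the GC trend removed, -0.467 without 3 h replicate 1 and, of opposite sign, 0.0614 without 3 h replicate 2 (p = 0.272). At 24 h it was -0.473, with p = 0.0749 with an estimated correlation, -0.235 with span limits of 50 kb and 20 kb, and -0.499 to -0.454 with 1 library left out.

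Among 292 values of named genes, direction and call stayed in 292 with DESeq2 size factors, 281 with total counts, 291 without a count filter and 290 with the GC trend removed, and in 288 of 289 with the DESeq2 Wald test. With 1 library left out, 2184 values kept direction and call, 132 lost the call and 20 gained one. Of 63 list results, 63 stayed with DESeq2 size factors, 61 with total counts, 55 without a count filter, 56 with the GC trend removed, 52 with fry and 50 with an estimated correlation, and with 1 library left out 471 stayed, 19 lost the call and 14 gained one.

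No shared effect of replicate number was seen, since deviations from the group means correlated at -0.087 to 0.0306 between groups. These values cannot show whether replicates of the same number were handled together, since a small shared effect could go unseen. With a replicate block the counts of genes were 8, 5273, 4061, 4749 and 7314 in the order above, and of the named genes JUNB at 30 min lost its call (adjusted p = 0.0829).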

Other observations

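The groups of transcription factors, the processed pseudogenes and the fits without both 3 h libraries were looked at only after the data were seen.

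Transcription factor families were taken from the family given for each gene in the deposited table, and 14 families had at least 10 tested members. Of 490 C2H2 zinc finger genes, the largest family, 236 fell and 13 rose at 3 h, with a median log2 fold change of -0.66, or -0.87 with total-count scaling (camera adjusted p = 2.61e-10, and adjusted p = 0.0521 with an estimated correlation). At 24 h 156 of them were higher and 30 lower, with a median of 0.39 (adjusted p = 3.15e-07, and adjusted p = 0.195 with an estimated correlation). Against 3 h, 336 were higher and 12 lower at 24 h, with a median of 1.10 (adjusted p = 3.35e-18, and adjusted p = 0.0307 with an estimated correlation). RLF went from -2.43 at 3 h to 0.65 at 24 h, ZNF443 from -2.19 to 0.73, ZNF420 from -1.40 to 1.11 and ZFP30 from -0.74 to 2.44. The family median was -0.59 and -0.72 in the 3 h libraries and 0.38 and 0.39 in the 24 h libraries. Genes of this family made up 13.4% of the genes that were lower at 3 h and higher at 24 h, against 3.24% of all genes tested. At 3 h the ARID family had 11 of 15 genes lower and none higher, with a median of -1.15 (adjusted p = 1.32e-09, and adjusted p = 0.0406 with an estimated correlation). The ZBTB family had 28 of 39 lower and 2 higher, with a median of -0.79 (adjusted p = 8.86e-07, and adjusted p = 0.0367 with an estimated correlation). The E2F, ETS and Homeobox families also fell and passed both ways, with camera adjusted p values of 0.0367, 0.0376 and 0.0376 with an estimated correlation. The HMG, MYB and THAP families did not pass with the preset (0.16, 0.0997 and 0.547), and the other families passed with the preset only.

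Without both 3 h libraries in the fit, 52 genes were higher and 172 lower at 30 min. Among the higher were IER2 (1.26), FOSB (0.90), KLF2 (0.95) and ZFP36 (0.92), all members of the immediate early list. ZFP36 promotes decay of AU-rich mRNAs. Among the lower were MYLIP (-1.06), a ubiquitin ligase, MED26 (-1.05), a Mediator subunit, HAS2 (-0.97) and INO80D (-0.91), a subunit of a chromatin remodelling complex. EIF3CL (3.44) and U2AF1L5 (2.83) were also called higher and U2AF1 (-1.01) lower. These have near-identical copies, so that their counts cannot be assigned with certainty. Transcription factors were 22.1% of the lower genes, 15.4% of the higher genes (8 of 52) and 7.14% of the genes tested.

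Processed pseudogenes had 102 higher and 19 lower of 482 at 3 h, with a median of 0.37, or 0.16 with total-count scaling. Processed pseudogenes are copies of the mRNAs of other genes. Reads from those genes were not separated from theirs, so that these counts cannot be assigned with certainty.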
